A study of Homo sapiens with 20 samples.

How the data were processed

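Total RNA of BEAS-2B cells was sequenced, per the labels, from a TruSeq RNA kit, and 20 libraries in 7 groups were analysed here. The authors deposited for each library raw read counts per RefSeq gene (25411 genes), with no normalisation. Per the file headers an RPKM value stands beside each count, computed by the authors per kilobase and library size. The authors also deposited 10 comparison tables with mean RPKM, a log2 ratio of nickel over control and test columns. The log2 ratios were made by the authors and are shrunken towards 0 against the ratio of the RPKM columns. In 2 deposited tables, those of the 3-day exposures, the columns hold p-values and Benjamini-Hochberg adjusted p-values. In the other 8 deposited tables the column named as a p-value holds a signed test score, and the column named as adjusted equals the 2-sided normal p-value of that score, so it is unadjusted. The submitters' processing notes name STAR 2.4, DESeq and DESeq2 and the builds GRCh37 and hg19. The roles of these tools, the way reads were counted and the strand of the library are not given in the sources used here. Coordinates in the text are those of the deposited files.

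Read counts were the basis of every comparison. In 2 libraries 28 gene symbols had been changed by a spreadsheet, and libraries were joined by RefSeq identifier. Totals per library ran from 8609243 to 88848786 reads, a ratio of 10.3. All 190 pairs of libraries were compared by their counts and correlation (r from 0.908 to 0.995), and no pair agreed as closely as counting error alone would give (lowest chi-square per degree of freedom 9.95). The lowest value was that of Ni_6W replicate 2 with Ni_6W+2W replicate 2, followed by Control_3D replicate 3 with Control_6W replicate 1 (12.39). Both pairs cross groups and were closer than any pair of the same group (12.58 or more). The 14 libraries that are not clones were fitted together with 1 mean per group in edgeR 4.0.16 (TMM normalisation, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood F test) in R 4.3.3. The biological coefficient of variation was 29.7%. Clones were fitted with Control_6W or with Ni_6W+2W alone, with the clones as replicates (coefficient of variation 24.7% with Control_6W). p-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. The direct comparisons were each nickel group against its control, Ni_3D+14D against Ni_3D, Ni_6W+2W against Ni_6W, clones against Ni_6W+2W, Control_6W against Control_3D, and the difference of the long and short responses, taken as Ni_6W minus Ni_3D and as Ni_6W+2W minus Ni_3D+14D, each against its control. A single clone has no replicate and was assumed to vary like the replicated groups. Overlaps between comparisons that share controls were set beside 20 simulated pairs of unchanged groups.

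The grouping, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. Named genes were ZEB1, CDH1, EPCAM, VIM, FN1, CDH2, SNAI2 and ZEB2 in all cases. To these were added, for each comparison with a control, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in 1 group, no overlap of libraries and a named symbol. Up to 4 called members of each called list followed, and the 8 genes that varied most between clones (SD of log2 CPM). Of 24 gene lists 23 had measured members: epithelial, mesenchymal, EMT transcription factors, metallothionein and zinc response, hypoxia and HIF, NRF2, ATF4 and unfolded protein response, heat shock, NF-kB, interferon, TGF-beta, cell cycle, p53 targets, cholesterol synthesis, chromatin enzymes, basal airway, ciliated and secretory airway, alveolar, endothelial, immune, neuronal, histones and ribosomal proteins. Mitochondrially encoded genes were not analysed here. Lists were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of a comparison. A gene without reads in a group was given a fold change against a floor of 3 reads over the group, and with 1 to 3 reads a ratio with its 95% interval.

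The tests were tried on simulated data with genes of known change in 3 draws per comparison. For 2-fold, 4-fold and 8-fold changes edgeR recovered 31.8%, 92.5% and 97% in Ni_3D, 15.4%, 82.6% and 97.5% in Ni_6W, 23.4%, 86.1% and 97% in Ni_6W+2W, and 63.7%, 94% and 98.5% in the clones. Genes called without a planted change averaged 9.33, 4.33, 6.67 and 13.3 in the same order by edgeR, and 48.7, 37, 30 and 47.3 by DESeq2. A raised list was called by camera in 3 of 3 draws in each of these comparisons, and among 60 unchanged lists 1 was called in Ni_6W+2W. Simulated genes were drawn independently of each other, so these draws cannot show how often camera calls unchanged lists whose members vary together. Alternatives tried were DESeq2 1.42.0, RLE size factors, no filter on low counts, replicate number as a block, only the groups compared, all 20 libraries in the clone fit, the other control group and leaving out each library. Further alternatives, chosen after seeing the data, left out or used alone parts of Control_3D, or left out Control_3D replicate 1 and Ni_3D replicate 1. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.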

Results

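BEAS-2B, an immortalised line of human bronchial epithelial cells, was measured by RNA sequencing in 20 libraries from cells exposed to nickel chloride and from unexposed controls. The libraries fall into 7 groups by their labels. Control_3D (n = 4) and Ni_3D (n = 2) are control and nickel-exposed cells of a 3-day exposure, and Ni_3D+14D (n = 2) is labelled as the 3-day exposure followed by a further 14 days. Control_6W (n = 2) and Ni_6W (n = 2) belong to a 6-week exposure, and Ni_6W+2W (n = 2) are cells washed and kept for 2 weeks in nickel-free medium after it. Ni_clone (n = 6) holds 1 library from each of 6 clones, grown without nickel from single colonies of the 6-week exposed cells. The labels give no control of the age of Ni_3D+14D or Ni_6W+2W, and no clones of unexposed cells. In these groups time in culture, handling or cloning cannot be told apart from past nickel exposure. Counts were given for 25411 genes, and the total per library ran from 8609243 (Control_3D replicate 4) to 88848786 (Ni_3D replicate 2). The other groups lay between 10581338 and 24181686 (Ni_6W), 16524990 and 20009974 (Ni_clone), 17454710 and 18610847 (Control_6W), 22292199 and 30903145 (Ni_3D+14D), and 23509793 and 33733301 (Ni_6W+2W). The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are CPM after TMM normalisation, as mean ± SD over the libraries of a group.

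The series title names ZEB1, a zinc-finger repressor of epithelial genes in epithelial-mesenchymal transition (EMT), on chromosome 10 at 31610064 to 31818742 in hg19. Its level was low in the 6-week controls (0.797 ± 0.267 CPM, n = 2) and was 17.0 ± 1.61 CPM in Ni_6W, 13.2 ± 4.6 CPM in Ni_6W+2W and 10.4 ± 2.93 CPM in the 6 clones. The 14 nickel libraries lay between 7.75 and 18.1 CPM. The 4 Control_3D libraries did not share a level: replicates 1 and 2 stood at 11.9 and 12.4 CPM and replicates 3 and 4 at 1.05 and 1.76 CPM. ZEB1 rose in Ni_6W by a log2 fold change of 4.40 (SE 1.03) and in the clones by 3.71 (SE 0.40), with adjusted p = 0.0497 and 0.00298 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In Ni_6W+2W the log2 fold change of 4.04 (SE 1.02) did not pass, with adjusted p = 0.256 by the same edgeR test and Benjamini-Hochberg adjustment. Against all 4 Control_3D libraries ZEB1 was 2.0-fold (SE 0.71 on the log2 scale) in Ni_3D and 1.61-fold (SE 0.72) in Ni_3D+14D, with adjusted p = 0.41 and 0.979 by edgeR after Benjamini-Hochberg adjustment. Without Control_3D replicates 1 and 2 the log2 fold changes were 3.36 and 3.06 and both passed (adjusted p = 0.002 and 0.0049 by edgeR with Benjamini-Hochberg adjustment), and without replicates 3 and 4 they were 0.17 and -0.13 and neither passed. The call in Ni_6W was lost without either Control_6W library and without Ni_6W replicate 1 (adjusted p = 0.103, 0.235 and 0.255 by edgeR with Benjamini-Hochberg adjustment), and that in the clones without Control_6W replicate 2 (adjusted p = 0.0738 by the same test). The RPKM in the authors' deposited tables was 2.81 for ZEB1 in the 3-day nickel column beside 0.218 in its control column, and the control column equals the mean of Control_3D replicates 3 and 4 alone.

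**Figure D1:**
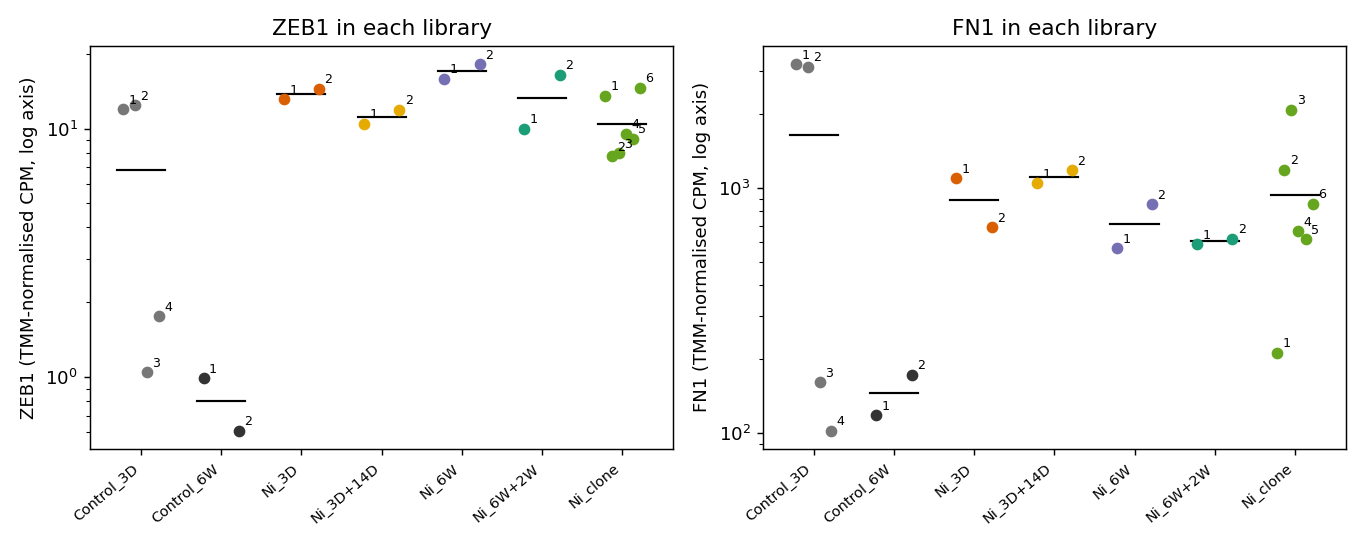
Each point is 1 library, numbered by replicate, with ZEB1 (left) and FN1 (right) in TMM-normalised CPM on log axes, and each bar is the mean of its group. The 14 nickel libraries held ZEB1 at 7.75 to 18.1 CPM, while the Control_3D libraries stood near 12 CPM in replicates 1 and 2 and under 2 CPM in replicates 3 and 4.

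Other EMT markers were fixed beforehand. FN1, which encodes the matrix protein fibronectin, followed the same split of the controls: 3185 and 3114 CPM in Control_3D replicates 1 and 2, beside 161 and 102 CPM in replicates 3 and 4. It was 145 ± 38.7 CPM in Control_6W, 711 ± 204 CPM in Ni_6W and 935 ± 643 CPM in the clones. Its log2 fold change was 2.29 (SE 1.30) in Ni_6W and 2.71 (SE 0.77) in the clones, with adjusted p = 0.285 and 0.0736 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so neither passed. Against Control_3D its log2 fold change was -0.87 (SE 1.11) in Ni_3D and -0.57 (SE 1.10) in Ni_3D+14D, and neither passed. Without Control_3D replicates 1 and 2 it was 2.76 and 3.07, and both passed as rises (adjusted p = 0.00223 and 0.00158 by edgeR with Benjamini-Hochberg adjustment). Without replicates 3 and 4 it was -1.82, which passed as a fall (adjusted p = 0.0239 by edgeR with Benjamini-Hochberg adjustment), and -1.51, which did not. SNAI2, another EMT transcription factor, averaged 8.52 ± 4.14 CPM in the clones beside 1.15 ± 0.0782 CPM in Control_6W (log2 fold change 2.89, SE 0.76, adjusted p = 0.057 by edgeR with Benjamini-Hochberg adjustment). Without clone 1 both FN1 and SNAI2 passed in the clones (adjusted p = 0.0328 and 0.00455 by edgeR with Benjamini-Hochberg adjustment). VIM, the mesenchymal intermediate filament vimentin, lay between 2080 and 3330 CPM in the nickel groups, beside 2630 CPM in Control_3D and 1930 CPM in Control_6W, and passed in no comparison. CDH2, the neuronal cadherin, was 127 ± 14 CPM in Ni_3D beside 209 ± 24.3 CPM in Control_3D, and ZEB2 was 65.2 ± 1.98 CPM beside 107 ± 16.2 CPM. Their log2 fold changes were -0.70 (SE 0.23) and -0.71 (SE 0.27), with adjusted p = 0.0895 and 0.135 by edgeR with Benjamini-Hochberg adjustment. CDH1, the epithelial cadherin, was at or under 2.05 CPM in 18 libraries and at 11.4 CPM in Control_3D replicate 1 and 29.1 CPM in Ni_3D replicate 1. EPCAM, an epithelial adhesion molecule, was 5.97 and 9.59 CPM in those 2 libraries, beside at most 5.37 CPM in the others. The same 2 libraries held transcripts that were near 0 elsewhere: TFF1 at 20.1 and 33.3 CPM, beside at most 0.116 CPM in any other library, and ESR1 at 3.52 and 10.7 CPM, beside 0 reads in every other library. TFF1 and ESR1 were chosen after their values were seen.

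Short exposure (Ni_3D against Control_3D) raised genes of the response to low oxygen together. CA9, a carbonic anhydrase induced by hypoxia, reached 496 ± 181 CPM (n = 2) beside 6.87 ± 5.42 CPM in the controls (n = 4). NDRG1, a stress-responsive gene, stood at 2150 ± 634 CPM beside 77.3 ± 36 CPM, and DDIT4, an inhibitor of mTOR signalling, at 643 ± 13.1 CPM beside 34.4 ± 25.7 CPM. Of 46 measured genes of the hypoxia and HIF list, 35 rose and 11 did not pass, and 42 rose when adjusted over the list alone, with a median log2 fold change of 1.93. The list as a whole stood apart from other genes by limma's camera (adjusted p = 1.38e-60 after Benjamini-Hochberg adjustment, and adjusted p = 0.0187 with an estimated correlation). The members with the smallest adjusted p were PGK1, phosphoglycerate kinase, which rose by 2.26 (SE 0.20), PFKFB3, which makes an activator of glycolysis, by 2.81 (SE 0.26), ALDOA, an aldolase, by 1.66 (SE 0.15), and P4HA2, a collagen prolyl hydroxylase, by 1.66 (SE 0.15), on the log2 scale. For each of these 4 genes, adjusted p = 0.000224 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

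The 8 largest rises in Ni_3D, by the rule fixed beforehand, were CA9 (log2 fold change 6.26), SPRY1 (5.39, SE 0.70), RORA (4.99), PPFIA4 (4.87, SE 0.47), NDRG1 (4.82, SE 0.69), BHLHE41 (4.54, SE 0.57), DDIT4 (4.25, SE 0.74) and FGF11 (4.21, SE 0.59). SPRY1 is an inhibitor of receptor tyrosine kinase signalling, RORA a nuclear receptor, and BHLHE41 a repressor of the circadian clock. Their adjusted p-values ran from 0.000245 for PPFIA4 to 0.0235 for RORA by edgeR with Benjamini-Hochberg adjustment. The 8 largest falls were BDKRB1 (-3.94, SE 0.70), SEMA3D (-3.42, SE 0.70), FGF1 (-3.42, SE 0.71), CCDC85A (-3.40, SE 0.69), OAS2 (-3.32, SE 0.71), DKK1 (-2.59, SE 0.53), ABI3BP (-2.50, SE 0.53) and OAS1 (-2.44, SE 0.62). BDKRB1 encodes a bradykinin receptor, FGF1 a fibroblast growth factor, and DKK1 a secreted inhibitor of Wnt signalling, which was 74.6 ± 31.3 CPM beside 452 ± 121 CPM. OAS1 and OAS2 are antiviral enzymes induced by interferon, and Control_3D replicate 3 stood apart from the other controls in both, with OAS2 at 46.5 CPM beside at most 14.2 CPM. Adjusted p-values of the falls ran from 0.0128 for BDKRB1 to 0.0463 for OAS1 by edgeR with Benjamini-Hochberg adjustment. Without Ni_3D replicate 1, and without replicate 2, none of these 8 falls passed by edgeR, nor did the rises of RORA and DDIT4. In hg19 CA9 lies on chromosome 9 at 35673915 to 35681154, NDRG1 on chromosome 8 at 134249414 to 134309547, DDIT4 on chromosome 10 at 74033677 to 74035797, and DKK1 on chromosome 10 at 54074041 to 54077417.

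Other lists moved less in Ni_3D. Of 28 genes of the ATF4 and unfolded protein response, 5 rose (8 adjusted over the list alone), among them DDIT3, a stress-induced transcription factor (1.38, SE 0.27), STC2, a secreted glycoprotein (2.08, SE 0.41), and VLDLR, a lipoprotein receptor (1.04, SE 0.26). Without Ni_3D replicate 2 DDIT3, STC2 and VLDLR were at 0.92, 1.93 and 1.22, and without replicate 1 at 1.70, 2.19 and 0.79. Of 22 p53 targets, 2 rose (4 adjusted over the list alone): DDB2, a DNA damage sensor (1.55, SE 0.26), and BTG2, an antiproliferative gene (1.70, SE 0.34). Without Ni_3D replicate 2 DDB2 was at 1.01 and BTG2 at 0.83. Among 9 neuronal genes the only rise was ENO2 (2.15, SE 0.21; 1 adjusted over the list alone), a glycolytic enolase that is also on the hypoxia list. Of 24 cholesterol synthesis genes 1 fell (8 adjusted over the list alone), of 20 heat shock genes the small heat shock protein CRYAB fell (-3.21, SE 0.64; 1 adjusted over the list alone), and of 32 interferon genes OAS1 and OAS2 fell (8 adjusted over the list alone). The lists' medians on the log2 scale were 0.89 (ATF4), 0.73 (p53), 1.51 (neuronal), -0.64 (cholesterol), -0.42 (heat shock) and -1.02 (interferon). By limma's camera with Benjamini-Hochberg adjustment these 6 lists had adjusted p = 1.05e-06, 0.000224, 0.00863, 3.7e-07, 0.00863 and 2.18e-07, in the same order. None of the 6 held when the correlation was estimated, where camera with Benjamini-Hochberg adjustment gave adjusted p = 0.397, 0.527, 0.33, 0.0972, 0.568 and 0.527 with an estimated correlation.

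The remaining lists were not called in Ni_3D by camera with Benjamini-Hochberg adjustment. For EMT these were the epithelial list (2 of 49 rose, 3 adjusted over the list alone; median 0.86, adjusted p = 0.0598), the mesenchymal list (3 of 40 fell, with 2 up and 6 down adjusted over the list alone; median -0.04, mean -0.42, adjusted p = 0.133) and the EMT transcription factors (0 of 13 called; median 0.27, adjusted p = 0.609). Beside the epithelial list, CDH1 was 29.1 CPM in Ni_3D replicate 1 and 0.0594 CPM in replicate 2. The lists for metal and oxidative stress were metallothionein and zinc response (1 of 7 rose, with 1 up and 1 down adjusted over the list alone; median 1.38, camera adjusted p = 0.212 after Benjamini-Hochberg adjustment) and NRF2 oxidative stress (2 of 22 rose, 4 adjusted over the list alone; median 0.25, adjusted p = 0.227). Signalling and growth lists were NF-kB and inflammation (1 of 28 rose; median 0.13), TGF-beta response (1 of 23 fell; median -0.15), cell cycle (2 of 35 fell; median -0.13) and chromatin modifying enzymes (1 of 37 rose; median 0.10), with camera adjusted p = 0.479, 0.15, 0.118 and 0.233 after Benjamini-Hochberg adjustment and the same members adjusted over the list alone. Markers of other cell types were basal airway (0 of 10 called; median 1.07), ciliated and secretory airway (1 of 6 rose; median 0.57), alveolar (0 of 6 called, 3 up adjusted over the list alone; median 0.77), endothelial (0 of 7 called; median 0.11) and immune (0 of 6 called; median 0.88), with camera adjusted p = 0.172, 0.36, 0.0677, 0.7 and 0.233 after Benjamini-Hochberg adjustment. Replication-dependent histones (0 of 15 called, 2 up adjusted over the list alone; median 0.57) and ribosomal proteins (0 of 26 called; median 0.13) had camera adjusted p = 0.172 and 0.609 after Benjamini-Hochberg adjustment.

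Across all 14927 genes tested, 422 rose and 225 fell in Ni_3D by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 338 and 111 changed by more than 2-fold, and DESeq2 called 1886. The count of 647 was 142 without Control_3D replicate 2, 136 without replicate 3, 227 without replicate 4, 139 without Ni_3D replicate 1 and 65 without Ni_3D replicate 2. It was 75 without the 2 libraries that held TFF1 and ESR1, 1174 without Control_3D replicates 1 and 2, and 121 without replicates 3 and 4. The authors' deposited table for this comparison lists 3276 genes at an adjusted p under 0.05, and its RPKM column for nickel lies outside the range of the 2 Ni_3D libraries in 42.9% of genes.

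**Figure D2:**
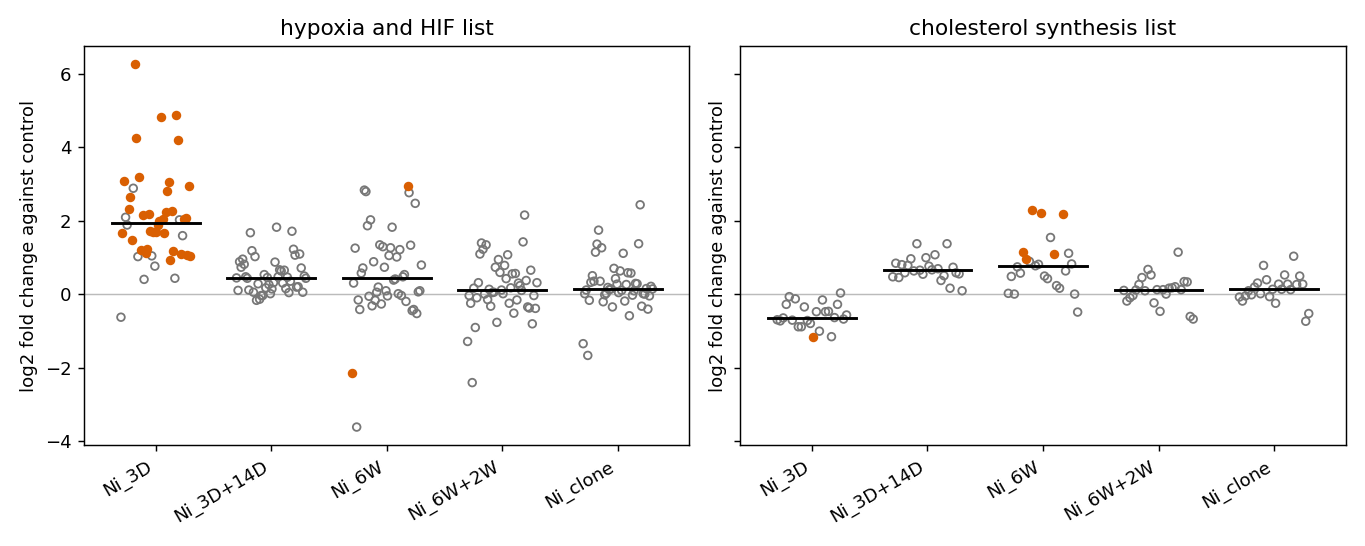
Each circle is the log2 fold change of 1 gene of the hypoxia and HIF list (left) or the cholesterol synthesis list (right) in a nickel group against its control, filled where the gene passed at an adjusted p under 0.05, and each bar is the median. The hypoxia median was 1.93 in Ni_3D and 0.45 in Ni_3D+14D, and the cholesterol median was -0.64 in Ni_3D, 0.65 in Ni_3D+14D and 0.76 in Ni_6W.

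Cells labelled as a further 14 days after the short exposure (Ni_3D+14D against Control_3D) showed raised cholesterol synthesis genes as a group. All 24 genes of that list had positive log2 fold changes, with a median of 0.65; none passed over all genes and 19 rose when adjusted over the list alone. Camera with Benjamini-Hochberg adjustment gave adjusted p = 5.94e-32 for the list, and adjusted p = 0.00115 with an estimated correlation. The hypoxia and HIF list had a smaller median of 0.45 (1 of 46 adjusted over the list alone), NF-kB and inflammation genes 0.46 with 26 of 28 positive, heat shock genes -0.40 with 20 of 20 negative, and cell cycle genes -0.11 with 27 of 35 negative. Camera with Benjamini-Hochberg adjustment gave adjusted p = 7.26e-10, 0.000488, 0.000162 and 0.00668 for these 4 lists, and adjusted p = 0.415, 0.556, 0.556 and 0.306 with an estimated correlation. No single gene passed: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14927 genes, with 613 at an unadjusted p under 0.05, and DESeq2 called 16. Those 613 are fewer than that threshold would give by chance. Leaving out any of the 6 libraries in turn also gave 0 by edgeR, and leaving out Control_3D replicates 1 and 2 gave 112.

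The change from Ni_3D to Ni_3D+14D was tested directly. Hypoxia genes were lower in Ni_3D+14D and cholesterol genes higher. Of 46 hypoxia and HIF genes, 11 fell and 35 did not pass, and 37 fell and 1 rose when adjusted over the list alone, with a median log2 fold change of -1.41. Its members included PFKFB3 (-2.51, SE 0.33), ENO2 (-1.87, SE 0.26), PGK1 (-1.80, SE 0.25) and ALDOA (-1.57, SE 0.19), all of glycolysis or its control. Of 24 cholesterol genes, 7 rose and 17 did not pass, and 22 rose when adjusted over the list alone, with a median of 1.12. Among them CYP51A1, a sterol demethylase, rose by 1.56 (SE 0.25) and FDFT1, squalene synthase, by 1.48 (SE 0.21). Adjusted p-values of these 6 genes ran from 0.00654 for ALDOA to 0.0295 for CYP51A1 by edgeR with Benjamini-Hochberg adjustment. Both lists held by camera with Benjamini-Hochberg adjustment (adjusted p = 5.81e-45 and 7.62e-41) and with an estimated correlation (adjusted p = 0.0213 and 0.000589). POSTN, the matrix protein periostin, was the only rise among 40 mesenchymal genes (6 adjusted over the list alone; median 0.29), on 40 reads in Ni_3D+14D and 1 in Ni_3D, a ratio of 101 (95% interval 17.1 to 4090, counting error only). Interferon genes (median 0.91, 31 of 32 positive), p53 targets (median -0.91, 22 of 22 negative, 7 fell adjusted over the list alone), ATF4 genes (median -0.63, 24 of 28 negative) and neuronal genes (median -0.94; ENO2 fell, 2 adjusted over the list alone) also stood apart. With the mesenchymal list first, these 5 had camera adjusted p = 0.000464, 3.83e-08, 3.83e-08, 6.99e-06 and 0.0475 after Benjamini-Hochberg adjustment, and adjusted p = 0.223, 0.526, 0.485, 0.508 and 0.508 with an estimated correlation. In all, 18 genes rose and 20 fell by edgeR with Benjamini-Hochberg adjustment. The count of 38 was 9 without Ni_3D replicate 2, 0 without Ni_3D+14D replicate 1 and 1 without Ni_3D+14D replicate 2, where 450 genes passed by DESeq2 on all libraries and 1876 had an unadjusted p under 0.05. It was 16 without Control_3D replicate 1 and Ni_3D replicate 1.

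After long exposure (Ni_6W against Control_6W), ZEB1, COL1A2, RPS6KA2 and GSTM2 were higher than in Control_6W, where they were near 0. EGR3, FOSB and DUSP2 were lower. TXNIP, an inhibitor of thioredoxin, was 1660 ± 1400 CPM (n = 2) beside 53.8 ± 13.2 CPM (n = 2). COL1A2, a collagen chain, was 28.0 ± 22.2 CPM beside 0.365 ± 0.258 CPM. FOSB, a growth-responsive transcription factor, was 1.27 ± 1.04 CPM beside 43.1 ± 8.97 CPM, and DUSP2, a phosphatase of MAP kinases, 2.96 ± 0.301 CPM beside 85.7 ± 15.9 CPM. The 8 largest rises were MRPL23-AS1, RPS6KA2, COL1A2 (6.24, SE 1.26), GSTM2 (5.17, SE 1.16), TXNIP (4.96, SE 0.89), ZEB1 (4.40, SE 1.03), ZNF608 (4.14, SE 0.97) and SERINC4 (4.12, SE 0.98). MRPL23-AS1 had 333 reads in Ni_6W and none in Control_6W, at least 112-fold higher against a floor of 3 reads over the group, but 14.3 CPM of it lay in replicate 1 and 0.44 CPM in replicate 2. It is annotated antisense to a gene and the strand of the reads is not stated, so its value is uncertain. RPS6KA2, a ribosomal S6 kinase, had 792 reads beside 2, a ratio of 400 (95% interval 110 to 3310). Intervals and floors cover counting error only. The 8 largest falls were EGR3 (215 reads in Control_6W and none in Ni_6W, at least 70.9-fold lower), FOSB (-5.00, SE 0.71), DUSP2 (-4.86, SE 1.09), PCDH7 (-4.69, SE 0.93), BDKRB1 (-3.74, SE 0.75), KCNK5 (-3.39, SE 0.72), FERMT1 (-3.06, SE 0.68) and PRR22 (-3.06, SE 0.60). Single libraries set several of these values. In Control_6W replicates 1 and 2 PCDH7 was 4.11 and 41.8 CPM, EGR3 2.03 and 10.8 CPM, and KCNK5 6.52 and 15.3 CPM, and without replicate 2 the log2 fold changes were -2.22 for PCDH7 and -2.66 for KCNK5. In Ni_6W replicates 1 and 2 SERINC4 was 16.9 and 3.61 CPM, and without replicate 1 its log2 fold change was 2.59, with TXNIP at 3.64, COL1A2 at 5.03 and GSTM2 at 3.89. FOSB was at -6.35 without Ni_6W replicate 1, and BDKRB1 at -4.92 without Ni_6W replicate 2. None of the 16 genes passed without Control_6W replicate 2 or without Ni_6W replicate 1, and none of the 8 rises without Control_6W replicate 1. EGR3 is an early growth response factor, PCDH7 a protocadherin and FERMT1 an integrin-linked kindlin. In hg19 TXNIP lies on chromosome 1 at 145438438 to 145442628, COL1A2 on chromosome 7 at 94023873 to 94060544, and FOSB on chromosome 19 at 45971253 to 45978437.

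Among the lists in Ni_6W, cholesterol synthesis stood highest in count. Of 24 genes 6 rose and 18 did not pass, and 14 rose when adjusted over the list alone, with a median of 0.76. HMGCS1 (2.29, SE 0.49), FDFT1 (1.14, SE 0.21) and FDPS (0.96, SE 0.18) are enzymes of the pathway, and INSIG1 (2.22, SE 0.37) is a sterol-regulated brake on it. The hypoxia and HIF list had 1 gene up and 1 down of 46 (5 up and 1 down adjusted over the list alone), with a median of 0.44, and its rise was PPFIA4 (2.93, SE 0.58). Camera with Benjamini-Hochberg adjustment gave adjusted p = 4.8e-09 for cholesterol synthesis and 0.0142 for hypoxia, and adjusted p = 0.0736 and 0.722 with an estimated correlation. Lower medians were found for NF-kB and inflammation (-0.72, 0 of 28 called, 1 down adjusted over the list alone), TGF-beta response (-0.43, 0 of 23 called), heat shock (-0.51, 0 of 20 called) and cell cycle (-0.35, 0 of 35 called, 4 down adjusted over the list alone). These 4 had camera adjusted p = 0.008, 0.0215, 0.0414 and 0.008 after Benjamini-Hochberg adjustment, and adjusted p = 0.722, 0.722, 0.722 and 0.238 with an estimated correlation. Of 13 EMT transcription factors 2 rose, ZEB1 among them, and the list was not called (median 0.23, camera adjusted p = 0.276 after Benjamini-Hochberg adjustment). Metallothionein and zinc response genes had a median of -1.21 (0 of 7 called, 1 down adjusted over the list alone; camera adjusted p = 0.0782 after Benjamini-Hochberg adjustment), and in this list the 2 Control_6W libraries differed: MT1X was 4.33 CPM in replicate 1 and 72.4 CPM in replicate 2, and MT2A 202 and 749 CPM.

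Several of these genes differed between the control groups. In Control_3D replicates 1 and 2, without nickel, COL1A2 was 12.7 and 8.88 CPM and RPS6KA2 4.68 and 4.12 CPM. ZEB1 was 11.9 and 12.4 CPM there and GSTM2 1.90 and 1.62 CPM. Over the Control_3D libraries FOSB was 2.21 to 5.03 CPM and EGR3 0.117 to 0.892 CPM, while DUSP2 was 36.7 to 74.8 CPM. In all, 187 genes rose and 181 fell in Ni_6W by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 179 and 163 changed by more than 2-fold. Every gene called in this comparison had adjusted p = 0.0497, the smallest value that edgeR with Benjamini-Hochberg adjustment gave here, so the calls sit at the threshold. The count of 368 was 0 without Control_6W replicate 2, 0 without Ni_6W replicate 1 and 2871 without Ni_6W replicate 2. With Control_3D replicates 1 and 2 as control it was 0, and with replicates 3 and 4 as control it was 543, of which 155 were among the 368. With only the compared groups in the fit it was 111, of which 38 were among the 368. With 3978 genes at an unadjusted p under 0.05, DESeq2 called 2098 on all libraries. The count was also 0 without Control_3D replicate 1 and Ni_3D replicate 1, libraries outside the comparison that enter the estimate of the spread and the filter (15198 genes tested without them).

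After wash-out (Ni_6W+2W against Control_6W), the genes called in Ni_6W kept their direction. All 187 that had risen were positive and all 181 that had fallen were negative, with medians of 1.14 and -0.90 on the log2 scale beside 1.92 and -1.40 in Ni_6W, and 141 and 156 had an unadjusted p under 0.05. These genes were chosen against the same Control_6W libraries, so part of the agreement in sign is built in. The simulated pairs below give no rate for it. Across genes the fold changes of both groups correlated at r = 0.82 with a covariance of 1.146, where 20 simulated pairs of unchanged groups against the same controls gave r = 0.52 and a covariance of 0.194; genes are not independent replicates. With Control_3D as the control of Ni_6W+2W, 183 and 180 of these genes had the same sign, with medians of 0.57 and -0.44 and r = 0.32. ZEB1 was 13.2 ± 4.6 CPM beside 17.0 ± 1.61 CPM in Ni_6W. Cholesterol synthesis genes had a median of 0.12 (0 of 24 called; camera adjusted p = 0.413 after Benjamini-Hochberg adjustment). Replication-dependent histones had a median of 1.02 (0 of 15 called, 1 up adjusted over the list alone), metallothionein and zinc response genes -2.38 (0 of 7 called, 5 down adjusted over the list alone), NF-kB genes -0.44 and p53 targets -0.48. In that order camera with Benjamini-Hochberg adjustment gave adjusted p = 0.000159, 0.00207, 0.00969 and 0.0059, and adjusted p = 0.681, 0.681, 0.715 and 0.715 with an estimated correlation. Beside the metallothionein list, SLC30A1, a zinc exporter, was 22.3 and 194 CPM in the 2 Control_6W libraries. No gene passed in the joint fit: edgeR with Benjamini-Hochberg adjustment called 0 of 14927, with 1956 at an unadjusted p under 0.05, and DESeq2 called 323. Libraries outside the comparison enter the spread of that fit. With only the compared groups in the fit edgeR called 39 genes, and without Control_3D replicates 1 and 2 it called 133. Without Control_6W replicate 1, edgeR called 117.

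Over the wash-out step (Ni_6W+2W against Ni_6W), cholesterol synthesis genes were lower as a group. Time in culture and handling cannot be told apart here from the removal of nickel. Of 24 genes of this list, none passed over all genes and 13 fell when adjusted over the list alone. In all, 22 of 24 were negative, with a median of -0.64. Camera with Benjamini-Hochberg adjustment gave adjusted p = 1.35e-17, and adjusted p = 0.00687 with an estimated correlation. Hypoxia genes (median -0.38, 36 of 46 negative), interferon genes (-0.29, 24 of 32 negative), cell cycle genes (0.14, 29 of 35 positive) and histones (0.82, 13 of 15 positive, 1 up adjusted over the list alone) had camera adjusted p = 0.000894, 0.0318, 0.000655 and 0.000407 after Benjamini-Hochberg adjustment, and adjusted p = 0.801, 0.801, 0.118 and 0.603 with an estimated correlation. ZEB1 differed by -0.37 (SE 0.85). Ni_6W replicate 2 lay nearer to Ni_6W+2W replicate 2 (SD of log2 ratios 0.20) than to Ni_6W replicate 1 (0.71). By edgeR with Benjamini-Hochberg adjustment 0 of 14927 genes passed, with 983 at an unadjusted p under 0.05, and DESeq2 called 7. Without Ni_6W replicate 2, edgeR called 1150.

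The largest rises in the 6 clones, taken as a group, were of genes near silent in Control_6W. ROBO1, an axon guidance receptor, had 1134 reads in the clones and none in Control_6W, at least 116-fold higher. PTPRN, a receptor-type phosphatase of secretory granules, was at least 95.4-fold higher, OSBPL6, an oxysterol-binding protein, at least 85.8-fold, and GALC, a lysosomal galactosidase, at least 79.6-fold. CADM3, a cell adhesion molecule, had a ratio of 710 (95% interval 196 to 5860) and MARK1, a microtubule-affinity kinase, 437 (78.3 to 17300). SNRPN and SNURF, from an imprinted locus on chromosome 15 at 25200135 to 25223729 in hg19, had ratios of 641 (115 to 25300) and 645 (116 to 25500), and the 2 genes share a transcript, so their reads cannot be told apart. These 8 were the largest rises, with adjusted p from 0.000519 for OSBPL6 and GALC to 0.0497 for ROBO1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest falls began with BCHE, butyrylcholinesterase, which had 466 reads in Control_6W and none in the clones, at least 507-fold lower. TLL1, a metalloprotease (-7.15, SE 0.72), MMP3, stromelysin (-4.62, SE 0.89), DCDC2 (-3.47, SE 0.48), FGF1 (-2.67, SE 0.54), C10orf67 (-2.56, SE 0.53), WNT7B, a Wnt ligand (-2.47, SE 0.48), and MAP2K3, a kinase upstream of p38 (-2.30, SE 0.36), followed. Their adjusted p-values ran from 0.00247 for TLL1 to 0.0306 for FGF1 by edgeR with Benjamini-Hochberg adjustment. Control_6W replicate 2 set most of these falls: replicates 1 and 2 were 3.78 and 24.1 CPM for BCHE, 0.712 and 17.6 CPM for MMP3, 14.2 and 87.8 CPM for FGF1, 2.14 and 15.4 CPM for C10orf67, 5.48 and 12.9 CPM for WNT7B and 230 and 861 CPM for MAP2K3. Without replicate 2 none of the 8 falls passed by edgeR, and the log2 fold changes were -0.97 (MMP3), -0.83 (FGF1), -0.54 (C10orf67), -1.73 (WNT7B) and -1.07 (MAP2K3). Of the 8 rises OSBPL6 and GALC passed without it (adjusted p = 0.00799 for both by edgeR with Benjamini-Hochberg adjustment) and the others did not, and without replicate 1 ROBO1 and CADM3 did not. Control_3D replicates 1 and 2 carried the same genes without nickel: MARK1 was 15.7 and 17.6 CPM there, SNRPN 13.5 and 14.4 CPM and OSBPL6 6.89 and 6.97 CPM, beside at most 0.04, 0.35 and 0 CPM in replicates 3 and 4. Several falls were also low there: BCHE was 0 and 0 CPM, TLL1 0.223 and 0.785 CPM and DCDC2 0.49 and 0.245 CPM. In replicates 3 and 4 these genes stood at 3.91 and 5.50, 4.34 and 3.04, and 3.95 and 4.33 CPM. WNT7B (3.14 and 2.55 beside 3.02 and 2.46 CPM) did not follow this split.

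EMT lists were called in the clones by camera at its fixed correlation and lost the call with an estimated correlation. Of 12 EMT transcription factors 3 rose and 9 did not pass (5 rose adjusted over the list alone), with a median of 1.23. ZEB1 rose by 3.71 (SE 0.40), TWIST2 by 1.93 (SE 0.32) and TWIST1 by 1.35 (SE 0.30). Of 38 mesenchymal genes 3 rose and 35 did not pass (8 rose adjusted over the list alone), with a median of 0.26. They were GAS1, a growth arrest gene (6.42, SE 0.65), COL5A1, a collagen chain (2.44, SE 0.47), and FBN1, fibrillin (2.30-fold, SE 0.17 on the log2 scale). Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.000681 for the EMT transcription factors and 0.00381 for the mesenchymal list, and adjusted p = 0.391 and 0.483 with an estimated correlation. Of 38 epithelial genes 1 rose and 1 fell, also adjusted over the list alone, and the list was not called (median 0.11, camera adjusted p = 0.898 after Benjamini-Hochberg adjustment). Of 14 histones 3 rose (5 adjusted over the list alone; median 1.21): HIST1H1C (1.38, SE 0.22), HIST1H2BD (1.34, SE 0.29) and HIST1H2BK (1.46, SE 0.32). Histone genes of the same family share near-identical sequence, so reads of their members are uncertain. Of 26 ribosomal protein genes RPL5 fell (-0.50, SE 0.12; 11 adjusted over the list alone; median -0.34). The zinc exporter SLC30A1 fell (-2.43, SE 0.55) among 7 metallothionein and zinc genes (3 adjusted over the list alone; median -1.45), where Control_6W replicate 2 alone held 194 CPM. Of 22 p53 targets ZMAT3 (-0.91, SE 0.21) and PLK3 (-1.46, SE 0.36) fell (3 adjusted over the list alone; median -0.26), and of 7 basal airway genes PDPN, podoplanin, rose (4.79, SE 0.63; 2 adjusted over the list alone; median 0.18). These 5 lists had camera adjusted p = 0.00029, 7.77e-06, 0.0173, 0.0309 and 0.0461 after Benjamini-Hochberg adjustment, and adjusted p = 0.483, 0.483, 0.735, 0.814 and 0.483 with an estimated correlation. The named members had adjusted p from 0.00262 for GAS1 to 0.0465 for PLK3 by edgeR with Benjamini-Hochberg adjustment. Without Control_6W replicate 2 none of them passed, and SLC30A1 was at -0.16 and PLK3 at -0.32. Without nickel, Control_3D replicates 1 and 2 stood near the clones in several of these: against them the clones' log2 fold change was -0.19 (SE 0.26) for ZEB1, -0.05 (SE 0.35) for GAS1, -0.10 (SE 0.23) for TWIST1 and -0.17 (SE 0.42) for COL5A1.

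In the clones 409 genes rose and 337 fell of 14172 tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 276 and 96 of them by more than 2-fold, and DESeq2 called 2002. The count of 746 was 1504 without Control_6W replicate 1 and 6 without Control_6W replicate 2, and without a clone it was 225 (clone 2), 283 (clone 3), 341 (clone 4) or 426 (clone 6). With Control_3D in place of Control_6W it was 10, with Control_3D replicates 1 and 2 as control 21, and with replicates 3 and 4 as control 1138. The clones and the washed population moved together: of the genes called in the clones, 408 of 409 rises and 336 of 337 falls had the same sign in Ni_6W+2W, with medians of 1.29 and -0.81 there. Both were set against Control_6W, so part of this agreement in sign is built in. Across genes their fold changes correlated at r = 0.88 with a covariance of 0.816, where unchanged groups against the same controls gave r = 0.64 and a covariance of 0.122 in 20 draws. With the clones set against Control_3D, r was 0.26 and the covariance 0.103. Of the genes called in Ni_6W, 60 rises and 79 falls were also called in the clones, where unchanged groups against the same controls shared 0 and 0 and independent lists would share 5.29 and 4.31. Neither value holds both the effects and the shared controls, so part of the excess may come from the controls. With the clones set against Control_3D, 3 rises and 0 falls were shared, with r = 0.31 and a covariance of 0.14. Across genes the fold changes of Ni_6W and the clones correlated at r = 0.79 with a covariance of 0.847, where unchanged groups against the same controls gave r = 0.62 and a covariance of 0.121 in 20 draws. Ni_3D and Ni_6W, which have separate control libraries, shared 32 rises and 16 falls, where independent lists would share 5.29 and 2.73. These controls are partly alike, since Control_3D replicates 3 and 4 against Control_6W gave 0 called genes. The rate for independent lists does not hold this, so part of the excess may come from the controls here too. Ni_3D and Ni_3D+14D share Control_3D: 364 of 422 rises and 179 of 225 falls had the same sign, with r = 0.30 and a covariance of 0.163 beside a simulated 0.34 and 0.088, and over splits of the 4 controls r ran from -0.22 to 0.35.

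**Figure D3:**
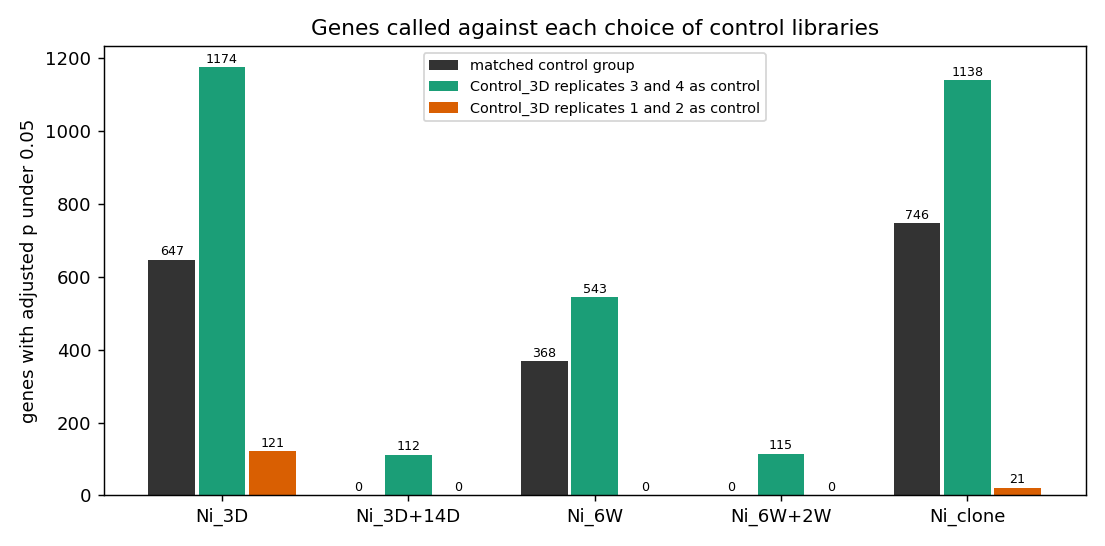
Bars give the number of genes with an adjusted p under 0.05 in each nickel group, against its own control group, against Control_3D replicates 3 and 4 and against Control_3D replicates 1 and 2. Against replicates 3 and 4 the clones had 1138 genes and against replicates 1 and 2 they had 21, beside 746 against Control_6W.

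Each clone was also set against Control_6W alone, with the spread taken from the replicated groups and a single clone assumed to vary like them. The 6 clones gave 27, 33, 37, 42, 29 and 40 genes of 14477 by edgeR with Benjamini-Hochberg adjustment, nearly all of them rises. Of 70 genes that rose in at least 1 clone, 10 rose in all 6 (among them ADCY1, DNAJA4, KIAA1244, MARK1, OSBPL6, RPS6KA2, SLC12A7, SNRPN and SNURF) and 25 in 1 clone alone. With the short-exposure groups added to the estimate of the spread, the counts were 4 in clones 1 and 6 and 0 in clones 2 to 5. Clones differed most in COL1A2, which ran from 0.28 CPM in clone 1 to 98.4 CPM in clone 6, COL5A3 (2.67 to 103 CPM), CLSTN2, a synaptic adhesion protein (0.41 to 65.4 CPM), FOSB (7.75 to 509 CPM), NCAM1, a neural adhesion molecule (0.18 to 17.7 CPM), and C19orf33 (0 to 17.2 CPM). The SD of their log2 CPM across clones was 2.31, 2.19, 2.14, 2.05, 2.03 and 2.19, in that order. The read-through loci TMX2-CTNND1 (29.3 CPM in clone 3, 20.4 CPM in clone 5 and 0 in the others, SD 2.92) and SPECC1L-ADORA2A (0 to 17.4 CPM, SD 2.37) share reads with the genes they join and are uncertain.

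Clones against the washed population (Ni_clone against Ni_6W+2W) differed in few single genes. NF-kB and inflammation genes had a median of 0.77, with 27 of 28 positive; none passed over all genes, 4 rose when adjusted over the list alone, and the list was called by camera but not with an estimated correlation. Endothelial markers (median 0.88, 7 of 7 positive), TGF-beta response genes (0.27), metallothionein genes (0.45), EMT transcription factors (0.10, 1 up adjusted over the list alone) and ribosomal proteins (-0.28, 22 of 26 negative) were also called. In the same order camera with Benjamini-Hochberg adjustment gave adjusted p = 2.43e-14, 0.00137, 0.0121, 0.0117, 0.0305 and 1.28e-05, and adjusted p = 0.15, 0.15, 0.604, 0.227, 0.277 and 0.735 with an estimated correlation. By edgeR with Benjamini-Hochberg adjustment 2 genes rose and 2 fell of 14273, with 943 at an unadjusted p under 0.05, and DESeq2 called 64. All 4, named after their values were seen, overlap other genes and are uncertain: NARR and MIR1181 had no read in Ni_6W+2W, SLMO2-ATP5E was 31.0 and 25.3 CPM there and at most 0.116 CPM in the clones, and TRIM6-TRIM34 differed by -6.46. The count was 2 without Ni_6W+2W replicate 2 or without clone 1, 2, 4, 5 or 6, and 6 without Ni_6W+2W replicate 1, where 4 were called on all libraries.

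Whether the response to long exposure differed from that to short exposure was tested as an interaction. The cholesterol list was higher in the long response (median 1.17, 24 of 24 positive, 17 up adjusted over the list alone) and the hypoxia list lower (median -1.32, 44 of 46 negative, 26 down adjusted over the list alone). Camera with Benjamini-Hochberg adjustment gave adjusted p = 3.92e-30 and 9.72e-33, and adjusted p = 0.00176 and 0.0476 with an estimated correlation. For the later groups (Ni_6W+2W effect minus Ni_3D+14D effect), of which only Ni_6W+2W is described as washed, the cholesterol list was lower (median -0.53, 24 of 24 negative; camera adjusted p = 4.65e-15 after Benjamini-Hochberg adjustment, and adjusted p = 0.0141 with an estimated correlation). ZEB1 differed by 3.40 (SE 1.25) between the long and short responses, with adjusted p = 0.368 by edgeR with Benjamini-Hochberg adjustment. The controls enter this difference: Control_3D pools ZEB1 at 11.9 and 12.4 CPM (replicates 1 and 2) with 1.05 and 1.76 CPM (replicates 3 and 4). Its mean in the nickel groups was 13.8 CPM (Ni_3D) and 17.0 CPM (Ni_6W). EdgeR with Benjamini-Hochberg adjustment called 0 genes in the first interaction, with 1630 at an unadjusted p under 0.05 and 197 by DESeq2. The second gave 0 by edgeR, 290 at an unadjusted p under 0.05 and 2 by DESeq2. Those 290 are fewer than that threshold would give by chance. Without Ni_6W replicate 2 the first had 302 genes by edgeR, without Control_6W replicate 1 it had 45 and without Ni_3D replicate 1 it had 2, and the second had 8 without Control_6W replicate 1. Other lists called in these interactions lost their call with an estimated correlation and are given in the closing section.

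The control groups were compared by the same test (Control_6W against Control_3D), which pools the unlike pairs of Control_3D libraries. Set against Control_6W, replicates 1 and 2 gave 407 called genes by edgeR. Replicates 3 and 4 gave 0, with 540 at an unadjusted p under 0.05, fewer than that threshold would give by chance. Metallothionein and zinc response genes stood higher in Control_6W (median 2.33, 7 of 7 positive, 5 up adjusted over the list alone), and their level was set by replicate 2, with MT1E at 234 CPM beside 16.6 CPM in replicate 1 and HMOX1, haem oxygenase, at 211 beside 38.2 CPM. NF-kB (median 0.43, 1 up adjusted over the list alone), TGF-beta (0.29), p53 (0.15), hypoxia (0.14) and histone genes (-0.65) were called as lists too. In that order, metallothionein first, camera with Benjamini-Hochberg adjustment gave adjusted p = 2.77e-06, 0.000337, 0.0312, 0.0322, 0.0283 and 0.0113, and adjusted p = 0.723, 0.912, 0.912, 0.963, 0.963 and 0.912 with an estimated correlation. ZEB1 was lower in Control_6W by a log2 fold change of -3.12 (SE 0.94, adjusted p = 0.577 by edgeR with Benjamini-Hochberg adjustment). By that test 0 of 14927 genes passed, with 1240 at an unadjusted p under 0.05, and DESeq2 called 48. Without Control_6W replicate 1, edgeR called 134.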

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

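The test of depth in the last paragraph of this part, and the choice of the genes that show its pattern, came after the result was seen. The counts over other pairs of libraries and over all genes that low had no prediction written down. The gap test and the tests of interactions were planned.

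In groups of 4 or 6 libraries, the gap between an extreme library and its nearest neighbour, as a share of the group's range, was large in 10 of 58 tests. Chance flags about 1 in 20 groups. Among the controls these were CDH1 (0.973, Control_3D replicate 1 at 11.4 CPM), EPCAM (0.926, replicate 1 at 5.97 CPM), ZEB2 (0.907, replicate 4 at 83 CPM), DDIT4 (0.839, replicate 4 at 72.6 CPM), OAS2 (0.941, replicate 3 at 46.5 CPM) and OAS1 (0.874, replicate 3 at 19.9 CPM). Among the clones they were ROBO1 (0.65, clone 2 at 29.5 CPM), MARK1 (0.776, clone 1 at 4.26 CPM), COL1A2 (0.742, clone 6 at 98.4 CPM) and CLSTN2 (0.802, clone 4 at 65.4 CPM). COL1A2 and CLSTN2 were named because they vary between clones, so a gap in them is expected.

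Gene lists differed between the long and the short response when the difference itself was tested. For Ni_6W minus Ni_3D the medians on the log2 scale were -0.38 (epithelial), 0.29 (mesenchymal), -2.93 (metallothionein), -1.32 (hypoxia), -0.60 (ATF4), -0.86 (NF-kB), 1.33 (interferon), -1.22 (p53) and 1.17 (cholesterol). For Ni_6W+2W minus Ni_3D+14D they were 0.36 (EMT transcription factors), -2.54 (metallothionein), -0.17 (hypoxia), -0.99 (NF-kB), -0.22 (p53), -0.53 (cholesterol), -1.04 (endothelial) and 0.72 (histones). With an estimated correlation the calls of hypoxia and cholesterol in the first and of cholesterol in the second held, and the others were lost. The control groups enter these differences, and metallothionein genes were already higher in Control_6W than in Control_3D (median 2.33). The 2 Control_3D libraries at the nickel level of ZEB1 enter them too.

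CDH1 and EPCAM stood out in Control_3D replicate 1 and Ni_3D replicate 1, together with genes typical of oestrogen receptor-positive breast carcinoma lines, such as GATA3 (16.6 and 40.5 CPM, at most 0.348 CPM elsewhere), GREB1 (34.8 and 65.1, at most 4.59 CPM) and PGR (3.01 and 5.65, at most 0.199 CPM). CYP19A1, the aromatase gene, was 21.5 and 29.8 CPM there and had no read in any other library, and DSCAM-AS1 was 10.9 and 13.4 CPM. Greater depth is argued against, since ESR1 in Ni_3D replicate 2, the deepest library, was 0% of its level in Ni_3D replicate 1. RNA or cells of such a line may be the source. Of 17 markers listed before their values were seen, 6 had a median under 1 CPM in the other libraries. Of these 6, 4 (66.7%) were higher in both libraries than in each of the other 18, beside at most 1 in any other of the 190 pairs. Over all 3020 genes that low, 145 met the same test, and the highest other pair had 173, so the 6 markers carry the argument alone. Their margins were small. AGR3 had 2 and 5 reads in the 2 libraries, and Control_3D replicate 1 held SPDEF at 0.357, CLDN4 at 1.74 and MYB at 3.52 CPM. The highest other libraries stood at 0, 0.218, 1.62 and 2.28 CPM in these genes. Of the 11 listed markers with a median of 1 CPM or more, 2 were higher in both libraries and 9 were not, XBP1, MUC1 and ELF3 among them. An epithelial state of the BEAS-2B cells themselves cannot be told apart, since the basal airway list differed by a median of 0.45 over 7 members, between the bounds set before, and no biological explanation beyond it was tested.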

How the results depend on the processing

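The alternatives that drop or reuse parts of Control_3D or drop Ni_3D replicate 1 were chosen after seeing the data; the others were planned. In the order Ni_3D, Ni_3D+14D, Ni_6W, Ni_6W+2W and clones against their controls, edgeR called 647, 0, 368, 0 and 746 genes and DESeq2 1886, 16, 2098, 323 and 2002. DESeq2 gave 7 for Ni_6W+2W against Ni_6W (0 by edgeR), 450 for Ni_3D+14D against Ni_3D (38), 197 and 2 for the interactions Ni_6W minus Ni_3D and Ni_6W+2W minus Ni_3D+14D (0 and 0), 64 for clones against Ni_6W+2W (4) and 48 for Control_6W against Control_3D (0). RLE size factors left every count within 1.5 times, and no filter did so except for Ni_3D+14D against Ni_3D (59), the long interaction (10), clones against Ni_6W+2W (7) and the controls (1). Fitting only the groups compared gave 111 (Ni_6W), 39 (Ni_6W+2W), 243 (Ni_3D+14D against Ni_3D) and 1 (controls), and all 20 libraries 464 (clones) and 0 (clones against Ni_6W+2W). The other control group gave 1611 (Ni_3D), 584 (Ni_6W) and 10 (clones). Replicate numbers do not pair samples by the labels, and same-numbered libraries of nickel groups and their controls correlated little (r from -0.055 to 0.272). With the number as a block the counts were 92 (Ni_3D), 761 (Ni_6W), 128 (Ni_6W+2W), 1 (clones), 70 and 28 (interactions), 9 (clones against Ni_6W+2W) and 281 (controls); in the clones that fit keeps 1 residual degree of freedom. Leaving out 1 library gave 65 (without Ni_3D replicate 2) to 653 (Ni_3D), 0 to 0 (Ni_3D+14D), 0 to 2871 (Ni_6W, without Ni_6W replicate 2), 0 to 117 (Ni_6W+2W), 6 (without Control_6W replicate 2) to 1504 (clones, without Control_6W replicate 1), 0 to 1150 (Ni_6W+2W against Ni_6W), 0 to 34 (Ni_3D+14D against Ni_3D), 0 to 302 and 0 to 8 (interactions), 2 to 6 (clones against Ni_6W+2W) and 0 to 134 (controls), with a lone library assumed to vary like the other groups; the report names each library that moved a count. Without Control_3D replicates 1 and 2 the counts were 1174 (Ni_3D), 112 (Ni_3D+14D), 761 (Ni_6W) and 133 (Ni_6W+2W), and FN1 turned to 2.76 in Ni_3D and 3.07 in Ni_3D+14D. Without replicates 3 and 4 Ni_3D had 121. Replicates 1 and 2 as control gave 0 (Ni_6W) and 21 (clones), and replicates 3 and 4 as control 543 (Ni_6W), 115 (Ni_6W+2W) and 1138 (clones). Without Control_3D replicate 1 and Ni_3D replicate 1 the counts were 75 (Ni_3D), 0 (Ni_6W), 16 (Ni_3D+14D against Ni_3D) and 1 (long interaction). Against replicates 1 and 2 these log2 fold changes of the clones changed sign: ZEB1 -0.19, ROBO1 -0.26, GALC -0.54, CADM3 -0.09, MARK1 -0.34, DCDC2 0.38, GAS1 -0.05, COL5A1 -0.17, TWIST1 -0.10, SLC30A1 0.32, ZMAT3 0.10 and PLK3 0.72, and PLK3 was 0.13 against all of Control_3D. The median count of a single clone was 35, and 0 with the short-exposure groups added. Camera called 70 lists and 8 with an estimated correlation. Among the values of named genes under these alternatives, 2001 of 2494 stayed on their side of the threshold, 445 fell short of it, 33 newly passed and 15 changed sign with a call before or after; values called in neither could change sign unseen by this count, as CDH1 did in Ni_3D (-2.19 without Control_3D replicate 1 and Ni_3D replicate 1). For the counts and signs above that moved, the cause was not tested. At these depths and group sizes 2-fold changes planted in Ni_6W were recovered in 15.4% of genes, and the part of depth in this was not separated.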

Other observations

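The tests of a wrong label and of depth for the Control_3D libraries, the tests between pairs of Control_3D libraries and of such pairs against Control_6W, the count of genes that are on or off by library, and the cholesterol difference between Ni_6W replicate 2 and Ni_6W+2W replicate 2 were chosen after the result was seen. The predictions for another stock or batch, for thinning, for the distance between libraries and for cholesterol genes against the Ni_6W+2W mean were written down before their values were seen, and leaving out each library was planned.

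Control_3D replicates 1 and 2 stood at the ZEB1 level of the nickel libraries, and replicates 3 and 4 at that of Control_6W. Replicates 1 and 2 gave 315 called genes against 3 and 4 and 407 against Control_6W by edgeR with Benjamini-Hochberg adjustment. Replicates 3 and 4 against Control_6W gave 0, with 540 at an unadjusted p under 0.05, fewer than that threshold would give by chance. A Ni_3D library under a control label is argued against, since the hypoxia and HIF list differed by a median of -0.1 between the pairs of replicates, where Ni_3D exceeded replicates 3 and 4 by 1.65. Depth is argued against, since ZEB1 in replicate 3 had 8.58% of the reads expected at its depth (27 beside 315). Control cells of another stock or culture batch are a candidate explanation. Genes called up in the clones were higher in replicates 1 and 2 by a median of 0.88, 390 of 409 in the same direction. Genes called down differed by -0.33, beside 0 for other genes, so part of the clone changes may separate lots of cells and not nickel exposure. A Ni_3D+14D, Ni_6W+2W or clone library under a control label was not tested. The hypoxia list could not show it, with medians of 0.45, 0.12 and 0.15 against control in those groups. The clone genes cannot tell it from another stock.

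Taken library by library, 6 genes (CADM3, DNAJA4, OSBPL6, SLC12A7, SNRPN and SNURF) were under 1 CPM in Control_3D replicates 3 and 4 and in Control_6W and at or over 5 CPM in the other 16 libraries. No gene was the other way round, and 0 of the other choices among 4845 sets of 4 libraries had any such gene. SNRPN and SNURF share reads and count as a single locus.

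Ni_6W replicate 1 alone gave 2871 genes and replicate 2 alone gave 0 by edgeR, with 2420 at an unadjusted p under 0.05. Lower depth of replicate 2 is argued against, since replicate 1 thinned to that depth still gave 2780 (2752 to 2808 over 5 draws). For a washed-out library under the Ni_6W label, with the Ni_6W+2W libraries as labelled, cholesterol genes near the Ni_6W+2W mean were predicted. In Ni_6W replicate 2 they stood above that mean by a median of 0.72, 24 of 24 in that direction. This cannot decide the label, since Ni_6W replicate 2 is part of the comparison in which the list stood out. HMGCS1 of that list also ran from 25.3 to 156 CPM across clones grown without nickel. An exchange of labels between Ni_6W replicate 2 and Ni_6W+2W replicate 1 would also make Ni_6W replicate 2 washed-out. Its cholesterol median of 0.57 above Ni_6W+2W replicate 2 cannot decide this either, and no other washed library would then be left to give a spread. The distance test leaves it open too: Ni_6W replicate 1 was farther from Ni_6W+2W replicate 1 than Ni_6W+2W replicate 2 was, by 0.26 in the SD of log2 ratios, but it lay at 0.62 or more from every library, so that distance could not have come out otherwise. Ni_6W replicate 2 was nearer to Ni_6W+2W replicate 2 (SD 0.20) than to Ni_6W replicate 1 (SD 0.71), and no biological explanation was tested.

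Metallothionein and zinc response genes were several times higher in Control_6W replicate 2 than in replicate 1 (MT1X 72.4 and 4.33 CPM, MT1E 234 and 16.6 CPM), without exposure to nickel by the label. The read-through locus SLMO2-ATP5E was 16.8 CPM in Control_6W replicate 2, 33.9 CPM in Ni_6W replicate 2 and 31.0 and 25.3 CPM in Ni_6W+2W, and at most 2.95 CPM in the other libraries.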
